A study of Bos taurus with 2 samples.

How the data were processed

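Per the labels' protocols, whey from raw milk was centrifuged at 10000 g for 90 min at 4 °C, and the pellet was washed before RNA extraction. RNA from 3 milk samples was pooled in equal amounts per fraction, and 40 ng was labelled with Cy3 for a 1-colour Agilent miRNA array. The labels call this ultracentrifugation, a word usually used of higher forces. The force is given as labelled and is in doubt, and with it how completely vesicles were pelleted. The 2 arrays lay on 1 slide; a slide effect therefore does not separate the fractions.

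Per the file headers, the scanner images were extracted with Agilent Feature Extraction 10.7.3.1. The deposited scanner values are intensities: the processed signal equals the background-subtracted spot brightness to within 0.5 units, and no scaling between the arrays was applied. The software also gives a total signal intensity per miRNA, set to 0.1 where it did not call the miRNA detected. The deposited value table is in log2 units. It equals log2 of that total divided by 0.1, with a largest deviation of 6.2e-06 on the supernatant array, and is not scaled between arrays. Its column median is 0 on both arrays over 691 entries. What the authors did beyond this is not given in the sources used here.

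Each array held 42364 spots, of which 40200 were miRNA spots. Outlier spots, 1005 on the exosome array and 1032 on the supernatant array, were left out. Spots of a probe were averaged, then probes of a miRNA on the linear scale, 2 to 4 probes per miRNA. Values were divided by the 75th percentile of the probes detected on both arrays, then taken to log2. A probe was detected where at least 50% of its spots were well above background, and a miRNA where at least 1 probe was. The lowest signal of a detected miRNA was 8.21 on the exosome array and 7.04 on the supernatant array. The 1000 negative control spots, outlier spots included, read 4.77 ± 4.51 and 4.74 ± 8.18. Without outlier spots, the control called NegativeControl, which is part of these, read 4.67 ± 3.24 and 3.71 ± 3.02. The SD of a miRNA is the root mean square of its probes' SDs between spots. The median coefficient of variation between spots of detected miRNAs was 14.2% and 9.77%. A miRNA detected on 1 array has a lower bound only. With 1 array per fraction no test was run. Gene lists were compared with 10000 random lists matched on signal, as a description of these arrays.

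Rules for naming miRNAs were fixed before the data were examined. They took the 8 largest and 8 smallest differences of at least 2-fold, the 4 largest bounds per array, the 4 brightest miRNAs, and up to 3 of the brightest detected members of each of 12 lists. They gave 45 miRNAs. The names follow the array design. Of 670 names, 659 matched a RefSeq miRNA gene of ARS-UCD2.0, which gave names, overlaps and neighbours only. Probe positions are those of the array design in HGSC Btau_3.1. For 1261 of 1465 probes the interval is 1 base shorter than the probe, so its start or end is known to within 1 base.

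Alternatives covered the detection rule, 4 other scalings, normexp background correction with an offset of 50, the probe summary, the software's total signal, the value table, outlier spots, and odd or even spots. Scaling to labelling controls and to hybridisation controls was added after the data were seen. The steps were tested on simulated data, in which 400 miRNAs carried signal and 200 of them differed. After removal of a common offset of -0.20, all miRNAs detected on both simulated arrays at each simulated log2 difference of -3, -2, 0, 2 and 3 came back within 0.25 of it, and 0 of 270 miRNAs without signal were called. These were 45, 50, 200, 50 and 50 miRNAs. Simulated changes were balanced between directions, so this test does not bear on the choice of scaling. Simulated signals were drawn from the brighter detected values, and simulated noise lay far below the simulated detection cut-off. The 0 false calls were therefore set in advance, and neither result bears on miRNAs near the lowest detected signals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.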

Results

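Cow milk whey was split by centrifugation into a pellet, which the labels call exosome (small membrane vesicles released by cells), and the supernatant left above it. Small RNA in each fraction was measured on a 1-colour bovine miRNA microarray. The milk came from Holstein cows, and RNA from 3 milk samples was mixed in equal parts before labelling, so each fraction is represented by 1 array. There is no replicate check on any difference given here, and no p-value is given. The ± values are SDs between spots of 1 array and cover technical spread only. The array number limits the precision. Both arrays carried 670 bovine miRNAs on 1465 probes, with 60 spots per miRNA. No spot was saturated. Spots well above background made up 7.71% of the miRNA spots on the exosome array and 11.8% on the supernatant array.

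The first comparison asked which miRNAs were seen in each fraction. The exosome array detected 66 miRNAs and the supernatant array 85. Of these, 30 were detected on both, 36 on the exosome array only and 55 on the supernatant array only, which left 549 detected on neither. The exosome-only set held 5 members of the let-7 family, the miR-29 family members miR-29a, miR-29b and miR-29c, and 9 miRNAs from a list of common milk and mammary miRNAs. The supernatant-only set held 25 of the miRNAs first registered from cattle sequencing (miR-2284 to miR-2491, called bovine-numbered here) and the exosome-only set 3. That is 45.5% and 8.33% of these sets, against 40.4% of the miRNAs on the array. The calls depended on the detection rule. With spots that were positive and significant in place of well above background, 176 and 181 miRNAs were detected, 123 of them on both arrays. With every probe required, the exosome array detected 35, of which 13 were on that array only.

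**Figure D1:**
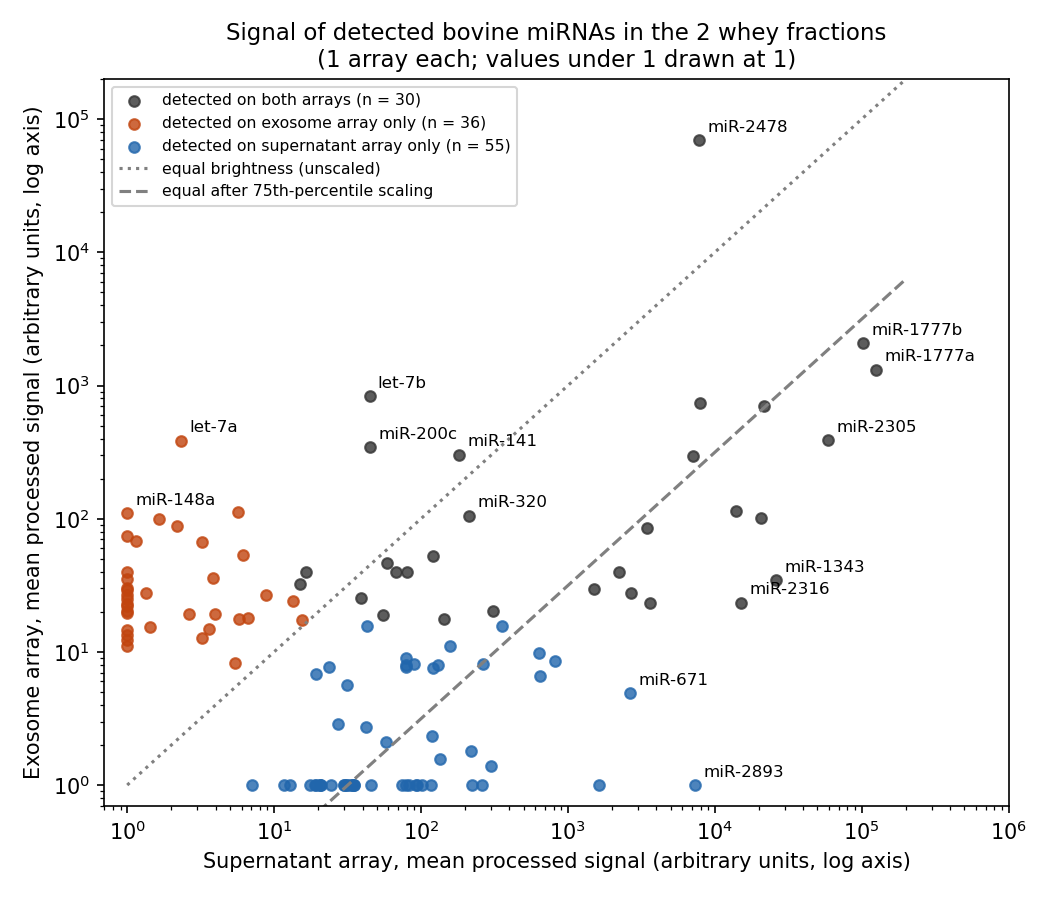
Mean processed signal of the 121 miRNAs detected on either array, in arbitrary units on log axes, with the supernatant array across and the exosome array upward. Points are single miRNAs, the dotted line marks equal brightness and the dashed line marks equality after 75th-percentile scaling. let-7b, miR-200c and miR-2478 lie above both lines, and miR-1343, miR-2316 and miR-2305 lie below both.

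The second comparison asked how far the 30 miRNAs detected on both arrays differed between the fractions. Brightness differed strongly between the arrays: the 75th percentile over the 53 probes detected on both was 473 on the exosome array and 15030 on the supernatant array. Scaling to it moved every log2 difference up by 4.99. After scaling, 16 miRNAs were at least 2-fold higher in exosome, 8 were at least 2-fold higher in supernatant and 6 differed by less. Without scaling the split was 5 and 21, with 4 under 2-fold. The median log2 difference, exosome over supernatant, was 1.30 with scaling and -3.69 without. Over the 7 scalings tried, 3 miRNAs were higher in exosome under each, 11 were higher in supernatant under each, and 16 changed direction or lay at 0 under at least 1. The 11 include miR-1584, at -0.34 after scaling, whose probes then had opposite directions. The differences ranged from -4.57 to 9.20 after scaling, while the median SD between spots of a difference was 0.19.

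The miRNAs higher in exosome under all 7 scalings were let-7b, miR-200c and miR-2478. let-7b, a member of a conserved family linked to cell differentiation, read 828 ± 47.6 on the exosome array (60 spots) and 44.6 ± 5.26 on the supernatant array (59 spots). Its log2 difference was 9.20 after scaling and 4.21 without. The longer of its 2 probes, AACCACACAACCTACTACC, is placed by the array design on chromosome 5 from 123308021 to 123308038 in HGSC Btau_3.1. miR-200c, an epithelial miRNA, read 343 ± 24.5 and 44.7 ± 4.47, with log2 differences of 7.93 and 2.94. The shorter of 2 miR-200c probes read only 4.42 ± 3.14 on the supernatant array, so miR-200c had 1 probe detected on both arrays. Its probe TCCATCATTACCCGG is placed on chromosome 5 from 10483408 to 10483421. In the RefSeq annotation of ARS-UCD2.0, used for names and neighbours only, the let-7b gene overlaps a protein-coding gene and lies within 10 kb of a let-7a gene, and the miR-200c gene lies beside the miR-141 gene in a long noncoding RNA. miR-2478 read 69241 ± 5134 on the exosome array and 7814 ± 636 on the supernatant array, with log2 differences of 8.14 and 3.15. Its probe TGGTGTCAGAAGTGGG is placed on chromosome 9 from 28787387 to 28787401, and no RefSeq gene overlaps the miRNA gene. The probes of miR-2478 differed from each other by more than 1 log2 unit.

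The other miRNAs with a large positive scaled difference were open to the scaling. miR-375 had a log2 difference of 6.28 after scaling, 1.29 without, and -0.30 when scaled to the labelling controls, RNAs spiked in before labelling. miR-423-5p had 6.10, 1.12 and -0.47 under the same choices. Each of these miRNAs had only 1 probe detected on both arrays. miR-141 had 5.73, 0.74 and -0.85. miR-92 had 4.66 after scaling and -0.33 without, and miR-664 had 4.38 and -0.61.

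The miRNAs with the largest supernatant excess kept their direction under all 7 scalings. miR-1343 read 34.5 ± 3.321 on the exosome array and 26097 ± 2105 on the supernatant array, a log2 difference of -4.57 after scaling and -9.56 without. Its 11-base probe CCCGCCCGGGG consists of G and C only and is placed on chromosome 15 from 65174970 to 65174979; in RefSeq the miRNA gene overlaps PDHX. The difference for miR-1343 varied by more than 1 log2 unit between its probes. miR-2316 read 23.4 ± 4.15 and 15182 ± 595, with log2 differences of -4.36 and -9.34. miR-2888 had -2.69 and -7.68, miR-2374 had -2.31 and -7.30, and miR-2305 had -2.25 and -7.24. miR-2328* had -1.96 and -6.95, but it became 1.003 when outlier spots were kept: 1 outlier spot on the exosome array read 52218. miR-1249 had -1.60 and miR-1777a -1.58 after scaling. With normexp background correction miR-1249 had -0.053 and miR-2374 -0.55, so both dropped below 2-fold and the supernatant count was 6. miR-1343 then had -3.20 and miR-2316 -2.58. The normexp offset of 50 exceeded the exosome signals of miR-1249 (27.8) and miR-2374 (23.1). On the log2 scale it raises such dim signals far more than their supernatant signals of 2678 and 3638. The drops of these miRNAs therefore cannot be told from an effect of the offset. On the supernatant array miR-1777a read 125084 ± 4036 and miR-1777b 102937 ± 4296. miR-1777b had a scaled difference of -0.64 and lay at 0 after quantile normalization.

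miRNAs detected on 1 array only have a lower bound, taken against the higher of the dim signal and the lowest detected signal of the other array. let-7a was at least 1737-fold higher in exosome after scaling and at least 54.7-fold higher without. let-7c was at least 504-fold and 15.9-fold higher, miR-148a, abundant in milk, at least 498-fold and 15.7-fold, and let-7f at least 452-fold and 14.2-fold. With normexp their log2 bounds were lower: 7.08 for let-7a against 10.76, and 5.74, 5.73 and 5.65 for let-7c, miR-148a and let-7f. All 36 exosome-only miRNAs had a bound above 1-fold both after scaling and without it. Scaled to the labelling controls, many of them had none: miR-19b, miR-23a, miR-23b-3p, miR-25, miR-27b, miR-29b, miR-34a, miR-99a, miR-106b and miR-140. The same held for miR-331, miR-345-5p, miR-362-5p, miR-2284d, miR-2284l and miR-2288. For the supernatant, 9 of the 55 had a bound after scaling and 54 without. The lowest detected signal after scaling was 0.0174 on the exosome array and 0.00047 on the supernatant array. A bound that would go the wrong way was left out, here and in the lists with bounds. The counts of bounds therefore follow largely from these floors and do not measure how far the miRNAs differ. miR-2893 led, at least 28.1-fold higher in supernatant after scaling and 891-fold without. It was followed by miR-671 at least 10.1-fold and 322-fold, miR-2348 at least 6.21-fold and 197-fold, and miR-2885 at least 3.02-fold and 96.0-fold. With normexp, miR-2348 and miR-2885 had no bound, and the log2 bounds of miR-2893 and miR-671, exosome over supernatant, were -1.81 and -0.37. Bounds of at least 2-fold under all 7 scalings were held by 9 exosome-only miRNAs and 5 supernatant-only miRNAs. With normexp, miR-2348, miR-2428, miR-2885 and miR-671 of these 5 fell short of 2-fold. The lowest detected signals, 8.21 on the exosome array and 7.04 on the supernatant array, also lay below the normexp offset of 50. The shrinking of bounds with normexp, in either direction, therefore cannot be told from an effect of the offset.

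Gene families chosen before the data were examined differed in detection. Of 10 let-7 miRNAs on the array, 5 were detected on the exosome array only, 1 on both and 0 on the supernatant array only. With dim sides at their bounds, the median log2 difference of the 6 was 8.90, at the 99.985th percentile of random lists of the same size matched on signal. let-7 and several other probes differ from another array miRNA by at most 1 mismatch, as 12 detected miRNAs do, so signal can be shared within families. Mismatches were counted from the first base of each probe. Matches at a shifted position, such as that between miR-29b and miR-29c, were missed, so more miRNAs may share signal. Of 5 miRNAs of the epithelial miR-200 family, 2 were on the exosome array only (miR-200a and miR-200b) and 2 on both, with a median log2 difference of 6.83 after scaling, 1.84 without and 0.25 with the labelling controls, where miR-141 turned negative. The 3 detected miR-29 miRNAs of 4, and the 4 detected of the 13 listed members of the miR-17-92 and paralogous clusters (miR-19b, miR-20a, miR-25 and miR-106b), were on the exosome array only. The list took no miRNA under the array name miR-92, whose matched RefSeq gene neighbours other cluster members and which was detected on both arrays. With bounds, the percentiles among matched random lists were 90.1 for miR-200, 85.6 for miR-29, 86.3 for miR-17-92 and 44.6 for miR-30. Without scaling they were 98.9, 96.5, 91.4 and 81.8, and 100 for let-7. Scaled to the labelling controls, miR-19b, miR-25, miR-106b and miR-29b had no bound above 1-fold. miR-20a in the latter was at least 308-fold higher after scaling and 9.70-fold without. Of 7 miR-30 miRNAs, 2 were on the exosome array only and 2 on both. The median of miR-30a-5p and miR-30d was 3.87 after scaling but -1.12 without, so its direction depends on the scaling.

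**Figure D2:**
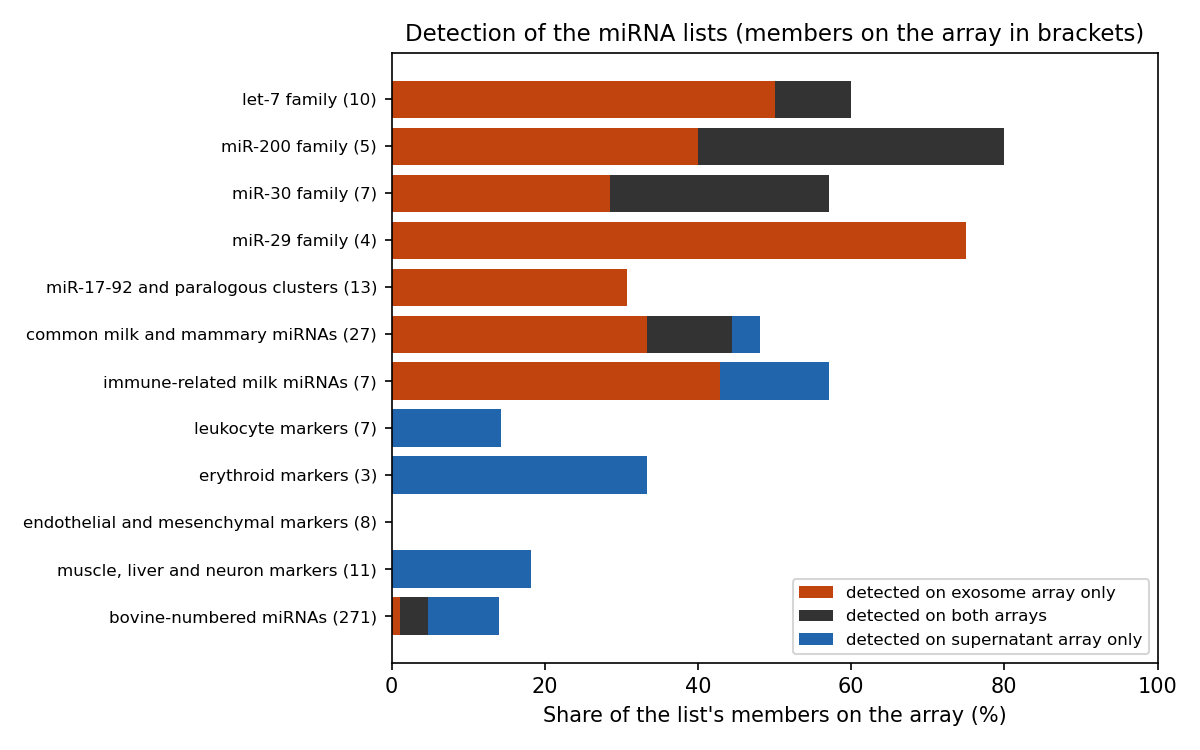
Share of each list's members on the array, in percent, that was detected on the exosome array only, on both arrays or on the supernatant array only, with the number of members in brackets. The let-7, miR-200, miR-30, miR-29 and miR-17-92 bars hold no supernatant-only part, and the leukocyte, erythroid and muscle, liver and neuron bars hold nothing else.

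Of 27 common milk and mammary miRNAs, 9 were on the exosome array only, 3 on both (miR-320, miR-375 and miR-423-5p) and 1 on the supernatant array only. The median of the 3 was 6.10 after scaling, 1.12 without and -0.47 with the labelling controls. Under each of these choices it is the value of miR-423-5p. That miRNA read 15.0 ± 4.00 on the supernatant array, where the lowest detected signal was 7.04. Only 1 probe of miR-423-5p, and likewise of miR-375, was detected on both arrays. With bounds, the list lay at percentile 97.4 of matched random lists after scaling and 99.6 without. miR-26a was at least 336-fold higher in exosome after scaling and 10.6-fold without. Of 7 immune-related milk miRNAs, 3 were on the exosome array only (miR-27b, miR-34a and miR-106b) and miR-223 on the supernatant array only. The median of the 3 with bounds lay at percentile 56.8 of matched random lists (75.9 without scaling, over 4), and miR-27b, miR-34a and miR-106b had no bound when scaled to the labelling controls.

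Of 29 markers of other cells, 0 were detected on the exosome array and 4 on the supernatant array. The 4 are 13.8%, against 12.7% of all miRNAs detected on the supernatant array and 9.85% on the exosome array. miR-223, a myeloid miRNA, was the 1 detected of 7 leukocyte markers, at 19.3 ± 4.23 on the supernatant array, and had a bound of 2.35-fold without scaling and none with it. miR-486, abundant in red blood cells, was the 1 detected of 3 erythroid markers, at 34.1 ± 6.20, with an unscaled bound of 4.15-fold and none with scaling. Of 11 muscle, liver and neuron markers, the muscle miRNAs miR-133a (78.9 ± 4.75) and miR-133b (74.8 ± 5.42) were detected, both on the supernatant array only. Their unscaled bounds were 9.60-fold and 9.11-fold, with none after scaling, and their probes differ by 1 mismatch, so the signal can be shared. None of 8 endothelial and mesenchymal markers was detected on either array.

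Of 271 bovine-numbered miRNAs, 10 were on both arrays, 3 on the exosome array only and 25 on the supernatant array only. The median log2 difference of the 10 was -0.39 after scaling and -5.38 without, and it turned to 0.18 with normexp background correction and to 0.40 with outlier spots kept. With the software's gene-level flag, which changes the miRNAs detected, the median was 1.19. With bounds, percentiles among matched random lists were 1.55 after scaling, over the 16 members with a value, and 0.080 without, over 37. Members without a bound are left out of each. The supernatant array detected mainly miRNAs with GC-rich, short probes. The median GC content of the longest probe was 46.9% for exosome-only miRNAs, 70.7% for those on both arrays, 71.4% for supernatant-only miRNAs and 47.4% for those on neither. Median probe lengths were 18, 13, 14 and 17 bases in the same order.

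**Figure D3:**
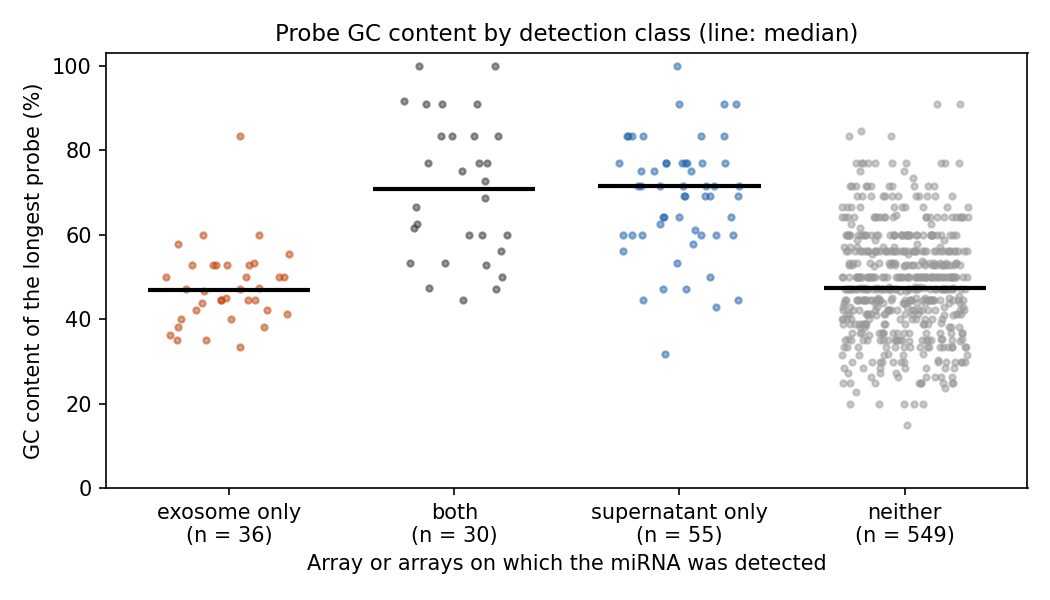
GC content of the longest probe of each miRNA, in percent, by the array or arrays on which it was detected, with the median as a line and 1 point per miRNA. The medians are 46.9% for the exosome array only, 70.7% for both arrays, 71.4% for the supernatant array only and 47.4% for neither.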

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

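All tests here were chosen after the results were seen, except the test of whether miR-2478 shifts the scaling. Spiked control RNAs differed between the arrays. The labelling controls dmr_285 and dmr_31a were brighter on the exosome array by 1.80 and 1.38 on the log2 scale, or 3.47-fold and 2.60-fold. The hybridisation controls dmr_3 and dmr_6 stood at 0.96-fold and 0.93-fold, exosome over supernatant. The scanner software's labelling metric lay out of its range on both arrays. Other control probes also stood out: hur_1 at 1.32 and hur_6 at 1.86 on the log2 scale, exosome over supernatant, while hur_2 stood at -0.27. hur_4 read 11.3 on the exosome array and was not detected on the supernatant array. mr_1 read 3.76 and miRNABrightCorner30 read 46.3 on the supernatant array, and neither was detected on the exosome array. These are control probes that the software called detected. mr_1 nevertheless read below the mean of 4.74 over the negative control spots of the supernatant array, outlier spots included. Without outlier spots, the control called NegativeControl read 3.71 there, close to mr_1.

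The first pattern is that each array held miRNAs missing or dimmer on the other; weaker labelling of the supernatant RNA bears on the exosome excess alone. Scaling to the labelling controls left 3 miRNAs detected on both arrays at least 2-fold higher in exosome, short of the 5 set as a limit. With lower bounds it left 12, above that limit. These 12 are by definition the miRNAs that stayed, 9 of them by a bound. For them the count argues only against a common loss of label of the size the controls show as the whole cause. Under all 7 scalings the smaller count of miRNAs at least 2-fold higher in 1 fraction was also 3, with 8 on the other side. With bounds there were 12 in exosome and 13 in supernatant, 9 and 5 of them by a bound. These were likewise picked as the miRNAs that kept their direction. The counts argue only against the choice among these 7 scalings as the whole cause for them. Scaling to the labelling controls gave the lowest exosome over supernatant values of the 7. The exosome counts of 3 and 12 therefore repeat those above and are not separate evidence. Bounds were added to both tests after the counts of 3 were seen. With normexp 7 of the 13 were still at least 2-fold higher in supernatant, while miR-2328* reversed with outlier spots kept. The losses with normexp cannot be told from an effect of its offset of 50, which exceeded dim exosome signals. Scaling stays open for the 16 miRNAs whose direction depends on it, as do labelling that depends on sequence and, untested with 1 array each, a difference between the fractions.

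The second pattern is the GC-rich, short probes of the supernatant array. A GC bias of that array may contribute. The supernatant-only median of 71.4% lay above all 10000 random lists, but at percentile 97.31 of lists matched on probe length, just short of the limit set for the test, so GC and length cannot be told apart. Bovine-numbered miRNAs made up 45.5% of the supernatant-only set, against a median of 43.6% among GC-matched lists, which neither shows nor excludes a part for the class.

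The third pattern is that miR-2478 held 87.9% of the summed brightness of detected miRNAs on the exosome array and 1.78% on the supernatant array. Brightness is not a count of molecules. Without its probes the ratio of the scaling factors, supernatant over exosome, moved from 31.8 to 38.8, or by 1.22 times. The higher ratio raises every scaled exosome over supernatant difference. The move lay between the limits of 1.1 and 1.5 set for the test, which therefore gave no verdict. Its probes start with TGG, the complement of the CCA at the end of tRNAs, and 1.2% of the other miRNAs on the array share this start. Signal from a tRNA end would give this start. A start of 3 bases is short, however, and the detected miR-223, miR-2328* and miR-23a share it. The match therefore does not single out a tRNA. tRNA sequences were not used here, so signal from miR-2478 and from a tRNA end cannot be told apart.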

How the results depend on the processing

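Scaling to the control RNAs was chosen after seeing the data; the other alternatives were set before. No paired analysis was possible because each group has 1 array and no test was run. With 1 array per fraction nothing could be left out in turn. Signal over background limits the calls near the lowest detected signals, where a changed detection rule changes the sets. Of the 45 named miRNAs, 41 had a difference or bound after scaling. Over the alternatives 527 of their values kept the sign, 38 changed it or became 0, and 9 were lost. A bound that would go the wrong way was left out, so a bound could only keep its sign or be lost. The 38 are therefore all measured differences, and the 527 overstate how stable the signs are. Of the 38, 29 were of miRNAs at least 2-fold apart after scaling, 8 of miR-2412 and 1 of miR-1777b, which became 0 with quantile normalization. The lost ones were bounds: miR-106b, miR-19b, miR-25, miR-27b, miR-29b and miR-34a with labelling controls, miR-2348 and miR-2885 with normexp, and miR-671 with the software's gene-level flag. With that flag miR-671 lost its bound only and was still at least 2-fold higher in supernatant. With outlier spots kept, miR-2328* became 1.003, through 1 outlier spot that read 52218. The percentile over all probes, the absence of scaling, the median and the control RNAs shift every difference of shared miRNAs by 1 amount, which accounts for the changes of sign under them. The value table is not scaled either, and the same miRNAs changed sign in it as without scaling. The cause was not tested for quantile normalization, whose shift differs between miRNAs. Nor was it tested for miR-2412 with normexp and with outlier spots kept.

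Detection with positive and significant spots gave 176 miRNAs on the exosome array, 181 on the supernatant array and 123 on both. With every probe well above background, the exosome array had 35, of which 13 on that array only. At least 2-fold higher in exosome were 5 with the 75th percentile over all probes, 5 without scaling, 5 in the value table, 3 with labelling controls and 5 with hybridisation controls. At least 2-fold higher in supernatant were 18, 21, 21, 24 and 19 in the same order, and 5 at a fold of at least 4.

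The median log2 difference of the miR-200 family was 2.09 with the percentile over all probes, 1.84 without scaling, 6.51 with quantile normalization, 7.08 with the median over shared miRNAs, 5.87 with normexp, 7.11 with the software's total signal, 1.88 in the value table, 0.25 with labelling controls, 1.92 with hybridisation controls and 7.37 with bounds. The miR-30 family had -0.86 with the percentile over all probes, -1.12 without scaling, 3.02 with quantile normalization, 4.12 with the median, -1.20 in the value table, -2.71 with labelling controls, -1.04 with hybridisation controls and 5.31 with bounds. The common milk list had 1.37 with the percentile over all probes, 1.12 without scaling, 4.08 with quantile normalization, 4.80 with normexp, 1.12 in the value table, -0.47 with labelling controls, 1.20 with hybridisation controls and 6.86 with bounds. The bovine-numbered list had -5.13 with the percentile over all probes, -5.38 without scaling, -2.07 with quantile normalization, -0.14 with the median, 0.18 with normexp, -0.15 with the total signal, -5.38 in the value table, 1.19 with the software's gene-level flag, 0.40 with outlier spots kept, -6.97 with labelling controls, -5.30 with hybridisation controls and 0.022 with bounds.

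With the percentile over all probes, miR-30a-5p became -0.77, miR-30d -0.96, miR-320 -0.77, miR-664 -0.35 and miR-92 -0.077. Without scaling the same 5 became -1.03, -1.21, -1.02, -0.61 and -0.33, and in the value table -1.18, -1.21, -1.02, -0.61 and -0.33. With labelling controls they became -2.61, -2.80, -2.61, -2.20 and -1.92, and miR-141 -0.85, miR-375 -0.30 and miR-423-5p -0.47. With hybridisation controls the 5 became -0.95, -1.13, -0.94, -0.53 and -0.25. miR-2412, at 0.049 after scaling, became -4.69 with the percentile over all probes, -4.94 without scaling and in the value table, -6.53 with labelling controls and -4.86 with hybridisation controls. It was -0.042 with quantile normalization, -0.0088 with normexp and -0.10 with outlier spots kept.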

Other observations

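Summed brightness, which is not a count of molecules, was concentrated in few miRNAs on both arrays. The 3 brightest held 92.2% of that of detected miRNAs on the exosome array and 65.2% on the supernatant array. miR-1777a and miR-1777b, with G- and C-rich probes, made up 51.8% on the supernatant array and 4.31% on the exosome array. The let-7 family made up 1.89% on the exosome array and 0.010% on the supernatant array, and the miR-200 family 0.96% and 0.051%. The 36 exosome-only miRNAs together held 2.08% of the exosome array's brightness, and the 55 supernatant-only miRNAs 4.02% of the supernatant array's.

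Probes of 1 miRNA did not always give the same difference. Of 22 miRNAs with at least 2 probes detected on both arrays, 5 had probes over 1 log2 unit apart: miR-1343, miR-1584, miR-2328*, miR-2478 and miR-320. In miR-1584 and miR-2881 the probes had opposite directions after scaling, and in 0 of the 22 without it.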
